A study of Mus musculus with 146 samples.

How the data were processed

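Polyadenylated RNA of bone marrow-derived macrophages was sequenced as 100 bp paired-end reads in 146 libraries, 1 per mouse, from outbred CFW mice of 16 weeks. The marrow cells had been differentiated for 5 days in medium conditioned by L929 cells, and per the labels no treatment was given. The labels give the sex, the plate, the lane and a collection date of each mouse. Per the submitters' processing notes, the reads were inspected with FastQC, aligned with TopHat2 2.0.11 to the mouse genome GRCm38 (mm10), counted per gene with HTSeq 0.6.1 and normalised with DESeq2.

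Both deposited tables were used. The first holds deposited raw counts, which were whole numbers for 22721 genes, and their column sums were taken as the depth of each library. The second holds deposited log2 values from the variance-stabilising transformation (VST) of DESeq2 for 10893 genes. Tested on the tables, the VST genes had at least 5 counts in every library, and no gene left out had more than 4 counts in every library. The VST value of a gene followed the log2 CPM (counts scaled to the total of the library) computed from the raw counts with a median Pearson r of 0.990 over libraries.

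Genes were named by Ensembl identifier from GENCODE M21, which matched 21899 of the 22721 identifiers. The remaining 822 held 0.160% of all counts. The annotation release used for counting is not stated in the notes. For each gene the share of its 50-mers that also occurs in another annotated gene, on either strand, was computed from 1 in 8 of the 50-mers. Genes with a share of 20% or more are marked as uncertain where named, since their counts may include or lack reads of the other gene.

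Libraries were grouped by labelled sex, 86 female and 60 male, and all were kept in every comparison unless said otherwise. Sex was tested with edgeR 4.0.16 in R 4.3.3, by the quasi-likelihood test on TMM-normalised counts after filterByExpr, with plate as covariate. Plate was tested by the same model over 6 plate coefficients, and the sex-by-plate interaction by a further model. Benjamini-Hochberg adjusted p under 0.05 was the threshold throughout. Gene lists were tested with camera from limma 3.58.1 at its preset inter-gene correlation and again with an estimated correlation, over the 26 lists with at least 3 tested members.

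Co-expression used the VST values after linear removal of plate and sex. For each of 22 lists with at least 4 members among the VST genes, the mean Spearman rho over all pairs was set against 10000 random lists of equal size matched on mean expression. The cholesterol score of a library was the mean of the z-scored residuals of the 20 cholesterol biosynthesis genes, scaled to an SD of 1. Each gene was regressed on the score with limma's moderated test, with plate and sex as covariates, and list members were tested against the score of the other members. The scores of 21 other lists were correlated with the cholesterol score by 100000 permutations, two-sided, with genes shared with the cholesterol list left out. These permutations ran over all libraries without regard to collection date. Their p values therefore do not allow for likeness between mice of the same date. Sex was permuted within plate to test the score difference between sexes, from residuals with plate alone removed. Modules came from average linkage clustering on 1 minus Pearson r, with the tree divided at a height of 0.6 and at least 30 genes per module, and were compared with lists by Fisher's exact test. A gene was called nearly silent in part of the mice when its median was at least 10 CPM and at least 5 libraries lay under 0.1 of that median.

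The lists, fixed before the data were examined, as were the comparisons, the main alternatives and the rule for naming genes, covered cholesterol biosynthesis, sterol sensing and uptake, LXR targets and sterol efflux, fatty acid synthesis, lysosome and lipid handling, interferon response, MHC class II, inflammatory cytokines and NF-kB targets, alternative activation, wound repair and matrix, mitosis, DNA replication, hypoxia and glycolysis, the integrated stress response, endoplasmic reticulum stress, heat shock, NRF2 targets, immediate early genes and macrophage identity. Further lists held markers of neutrophils and granulocyte precursors, dendritic cells, B cells, T and NK cells, erythroid cells, megakaryocytes, stromal cells, osteoclasts, and mast cells and basophils, and the Y-linked genes and X-linked genes escaping inactivation. By the naming rule, text on sex names the sex-linked lists, the 12 genes with the largest fold change in each direction among those past the threshold with a mean log2 CPM of at least 1, and up to 4 members per list by p. Text on the score names the 12 genes with the largest slope in each direction outside the cholesterol list and up to 4 members per list. The 6 genes with the smallest p for plate, the 15 most variable genes and up to 15 nearly silent genes complete the rule, which skips symbols of the form Gm plus digits and those ending in Rik. A gene named outside the rule is said to be so, and some that the rule would name are not reported here.

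The depth ranged from 14.5 to 121 M counts with a median of 43.8 M, and 5 libraries lay under 0.5 of the median. Errors are SD over mice, or the SE of the fitted model where stated, and differences between libraries in single genes include counting error. Tests were also run on simulated data of the same design, with unchanged genes drawn independently of each other. Real genes vary together, so the shares of false calls in the simulations need not hold for these data. The sex test recovered 87.1% of genes changed 1.2-fold and 100% of those changed 1.5-fold, with 2.69% false calls. The plate test recovered 60.0%, 87.7% and 98.5% of genes changed 1.2-, 1.5- and 2-fold, with 3.75% false calls. The interaction test recovered 99.5% of genes changed 4-fold, with 6.57% false calls, and the score test 98% of genes with a slope of 0.15, with 5.26% false calls. The clustering found 5 of 5 simulated modules, and the search for nearly silent genes found 100% of those made silent in 10 libraries.

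Alternatives covered DESeq2 size factors, limma voom, the DESeq2 1.42.0 Wald test, limma on the VST values, other filters on low counts, a prior count of 2 or 0.5 on the log2 CPM scale, other covariates (none, lane within plate, collection date, log2 total count), removal of 1 or 5 principal components, each plate left out, shallow libraries left out, each sex alone, and other clustering settings. Sets without the libraries whose sex-linked counts went against their label were also run, added after seeing the data except for the sex gene count. Other splits of the libraries were drawn for each count from a model, 60 for sex within plates, 30 for plate and for the interaction, and, added after seeing the data, 60 for sex within collection dates with date in the model and 30 for the interaction without the libraries against their label. Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 was used for the rest. Genotypes and the wound healing phenotype that the series mentions were not analysed here.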

Results

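Bone marrow-derived macrophages from 146 outbred CFW mice of 16 weeks were profiled by RNA sequencing, 86 from mice labelled female and 60 from mice labelled male. The series title names a macrophage cholesterol network and physiological wound healing, so the comparisons ask how cholesterol genes vary together over mice, which other programmes vary with them, and what sex and library batch contribute. Genotypes and wound phenotypes were not analysed here. Libraries sat on 7 plates, with 6 on plate 1 and 22 to 24 on each of the others, and the mice were collected under 28 date labels. Females had a mean depth of 46.9 ± 17.8 M counts (SD, n = 86) and males of 48.01 ± 20.6 M (SD, n = 60). The 10 most abundant genes of a library held 7.46% to 11.5% of its counts.

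The libraries carried high levels of macrophage transcripts. Lyz2, which encodes lysozyme, had a mean of 10002 ± 2318 CPM (SD, n = 146), Cd68, a lysosomal membrane glycoprotein of macrophages, 1749 ± 162 CPM, Csf1r, the receptor for macrophage colony-stimulating factor, 1707 ± 163 CPM, and Adgre1, the F4/80 antigen, 609 ± 80.8 CPM. Granulocyte and granulocyte precursor transcripts were present and spread widely between mice: Mpo, myeloperoxidase, had 157 ± 106 CPM and S100a8, a calcium-binding alarmin, 48.7 ± 37.4 CPM, whereas Ly6g had 0.0334 CPM. Markers of lymphocytes, red cells, and mast cells or basophils were close to the floor. Means were 0.0722 CPM for Cd3e, 0.0867 CPM for Hba-a1 (uncertain at 69.2% shared 50-mers) and 0.107 CPM for Cpa3, and the highest mean among those lists was 2.40 CPM for Cd79b. Among dendritic cell markers Itgax, which macrophages also express, had 28.7 ± 16.1 CPM and Flt3 2.57 CPM. Pf4, which is not restricted to platelets, had 58.4 ± 17.2 CPM in contrast to 0.0506 CPM for Gp9. Stromal collagen Col1a2 ranged from 0 to 28.0 CPM. These marker genes beyond the naming rule were chosen after their values were seen.

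Counts of sex-linked genes separated nearly all libraries by labelled sex. The summed Y-linked counts of Ddx3y, Uty, Kdm5d and Eif2s3y had a median of 296.9 CPM in the 58 libraries labelled male that carried them and of 0.0126 CPM in the 82 libraries labelled female that did not. In 4 libraries labelled female, numbers 5, 82, 85 and 86, the sum was 271 to 304 CPM, and in 2 libraries labelled male, numbers 57 and 59, it was 1 count each. Plate 8 held 5 of these 6 libraries and plate 10 held 1. The X-linked gene Eif2s3x, a translation initiation factor that escapes X inactivation and whose counts are uncertain, with 34.3% of 50-mers shared, had 23.5 ± 1.89 CPM (SD, n = 4) in the first 4 and 38.5 ± 2.22 CPM (SD, n = 2) in the other 2. The matching libraries had 36.2 ± 3.68 CPM (SD, n = 82) for females and 22.4 ± 2.22 CPM (SD, n = 58) for males. Male library 34 on plate 4 lay apart, with 86.5 CPM of Y-linked counts. Xist was not in the count table. All libraries were kept under their labels, and for some results values without these libraries are also given.

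**Figure D1:**
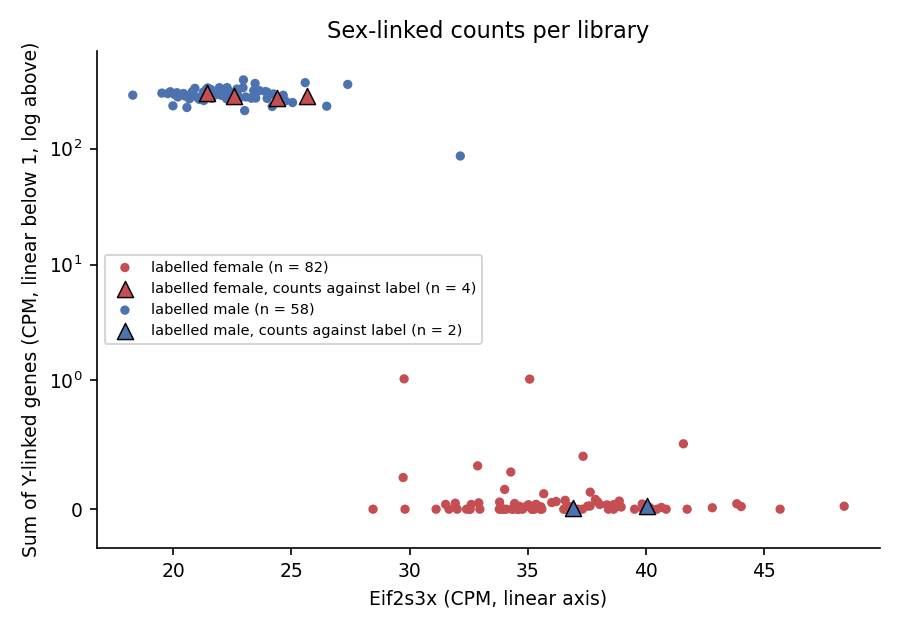
Summed CPM of 4 Y-linked genes (vertical axis, linear below 1 and logarithmic above) against CPM of Eif2s3x (horizontal axis) in each of 146 libraries, coloured by labelled sex. Triangles mark the 6 libraries against their label, and male library 34 is the single blue point at 86.5 CPM of Y-linked counts.

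Libraries labelled male carried more transcripts of Mrc1, the mannose receptor, and those labelled female more of Bmpr1a, a bone morphogenetic protein receptor. Mrc1 (chromosome 2, 14229392 to 14332057) had 254.5 ± 94.3 CPM in males (SD, n = 60) and 163 ± 77.01 CPM in females (SD, n = 86), a log2 difference of 0.64 ± 0.11 (SE, adjusted p = 3.09e-05). Bmpr1a (chromosome 14, 34410734 to 34503341) differed by -1.10 ± 0.11 on the log2 scale, male minus female (SE, adjusted p = 5.48e-14), from a mean of 6.61 CPM in females. Gdf3, a growth factor of the TGF-beta superfamily, differed by -1.28 ± 0.26 (SE, adjusted p = 0.000553). Other genes higher in males were Cbr2, a carbonyl reductase, at 0.55 ± 0.09 (SE), Adam19, a membrane metalloprotease, at 0.56, Tox2 at 0.53, Tns1, a focal adhesion protein, at 0.46, Cox6a2, a cytochrome c oxidase subunit, at 0.45, Lifr, the receptor for leukaemia inhibitory factor, at 0.40, and Xlr4b, uncertain at 57.4% shared 50-mers, at 0.44. Genes higher in females included Eya1 at -0.72, the thrombin receptor gene F2r at -0.67, the lysophosphatidic acid receptor gene Lpar1 at -0.65, the collagen lysyl hydroxylase gene Plod2 at -0.61, Fam171a1 at -0.60, the adaptor gene Grap2 at -0.59 and the Wnt receptor gene Ryk at -0.56. For these autosomal genes and Xlr4b the adjusted p lay between 5.48e-14 and 0.0429. Female means of F2r, Lpar1, Plod2, Fam171a1, Grap2 and Ryk were low, from 2.50 to 4.00 CPM. Whether such differences lie in the macrophages or in the share of other cells in the cultures was not tested.

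On the sex chromosomes, Ddx3y, an RNA helicase, averaged 138 ± 37.1 CPM in libraries labelled male and 6.06 ± 27.6 CPM in those labelled female (adjusted p = 6.40e-25), Eif2s3y 71.4 and 3.68 CPM, Uty 36.96 and 1.73 CPM, and Kdm5d 36.9 and 1.86 CPM. The female means include the 4 libraries labelled female that carried Y-linked counts. On plates without such libraries the female means of Ddx3y were 0.00690 to 0.0791 CPM. The X-linked escape genes were higher in libraries labelled female in 5 of 5 cases, with log2 differences of -0.62 for Eif2s3x, -0.59 for the histone demethylase gene Kdm6a, -0.48 for Kdm5c and -0.33 for Pbdc1. In all, 605 of 12060 genes differed between the labelled sexes by the edgeR test, 262 higher in males and 343 higher in females. Of these, 563 were autosomal, 37 X-linked and 4 Y-linked, and the autosomal ones had a median absolute log2 difference of 0.16. The difference exceeded 1.5-fold in 66 genes and 2-fold in 20. Without the 6 libraries against their label 926 genes passed, 601 of the 605 among them, and without male library 34 as well, an alternative chosen after seeing the data, 976. The count was 948 with lane within plate as covariate, 666 with collection date in place of plate, of which 429 were among the 605, 356 without plate 3, 230 without plate 4 and 298 without plate 7.

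Of the fixed lists 8 differed between the labelled sexes by camera at its preset correlation, and 2 of these, the Y-linked and X escape lists, also with an estimated correlation. For the other lists the calls ended with the estimate. Of 12 tested LXR targets and efflux genes, Apoe, the main apolipoprotein of macrophages, rose in males from 1083 ± 522 to 1410 ± 599 CPM (log2 difference 0.40, adjusted p = 0.0145) and Arl4c by 0.14 (adjusted p = 0.0261). Adjusted over the list alone 6 members were higher in males and 1 in females, and the list passed at an adjusted p of 0.00901, with adjusted p = 0.371 with an estimated correlation. The endoplasmic reticulum stress list was lower in males, with a median log2 difference of -0.13 and an adjusted p of 0.000177. Its member Manf, a secreted protein of the endoplasmic reticulum, fell by 0.17 (adjusted p = 0.0489), 8 of 11 members were lower adjusted over the list alone, and the estimated correlation gave an adjusted p = 0.604. Interferon response genes had a median of -0.24 and DNA replication genes of -0.10, both lists at adjusted p = 0.000177, and at adjusted p = 0.668 with an estimated correlation. Neither held a member past the edgeR threshold, adjusted over all genes or adjusted over the list alone, with 6 of 20 and 5 of 15 at an unadjusted p under 0.05, and 0 by limma voom or DESeq2. Cholesterol biosynthesis genes had a median of -0.06 and an adjusted p of 0.0242, with 0 of 20 members past the edgeR, voom or DESeq2 threshold, 0 adjusted over the list alone and 2 at an unadjusted p under 0.05. That list gave an adjusted p = 0.746 with an estimated correlation and 0.0782 without the 6 libraries against their label, for lists a set chosen after seeing the data.

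Stromal markers were lower in males as a list (adjusted p = 0.0142, and adjusted p = 0.668 with an estimated correlation). Col1a1 differed by -1.61 ± 0.38 (SE, adjusted p = 0.00354) and Col1a2 by -1.35 ± 0.36 (SE, adjusted p = 0.0123), from 2.34 and 3.05 CPM in females. Adjusted over the list alone 4 of 5 were lower, while limma voom called 0 of 5. The Y-linked and X escape lists, 4 of 4 and 5 of 5 members also adjusted over the list alone, passed with either correlation. Single members of other lists that passed were Cd163 (0.28), Timp2 (0.14), Atf5 (0.21), Adgre1 (0.11) and Npc1 (0.08), higher in males, and Mpo (-0.54), Ptgs2 (-0.45) and Me1 (-0.25, uncertain at 29.5% shared 50-mers), higher in females. Those lists did not pass, nor did the remaining ones, with adjusted p from 0.0944 to 0.991. For the sterol sensing, mitosis, hypoxia and dendritic cell lists, which did not pass, the median and mean differed in sign.

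The sex difference was not the same on every plate for 5 genes. These were Uty, Ddx3y, Kdm5d and Eif2s3y, and Tcam1, the last at adjusted p = 1.89e-05. Without the 6 libraries against their label, a set chosen after seeing the data, Tcam1 alone passed (adjusted p = 0.000116), as it rested on 1 library, male 38 on plate 4, with 25.9 CPM against a next highest of 0.825 CPM. Limma voom also called 1 gene.

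Of the 6 genes with the smallest p between plates, all but Gm9493 had their highest mean on plate 1. Rps16 (chromosome 7) had a mean of 30.7 ± 4.54 CPM on plate 1 (SD, n = 6) and of 2.78 to 3.73 CPM on the others, and Aldoart2, a retrogene of aldolase A, 23.0 ± 3.36 CPM on plate 1 and 2.31 to 3.19 CPM elsewhere. Rps7 had 21.8 CPM on plate 1, 7.91 CPM on plate 10 and 3.26 to 4.23 CPM on the rest. The 3 others among the 6 genes with the smallest p were the unnamed loci Gm10222, Gm9493 and Gm5263. Rps16 and Rps7 are uncertain, with 35.5% and 24.4% of 50-mers shared, as are the 3 unnamed loci, with 77.2% to 100%. In all 9021 of 12060 genes, 74.8%, differed between plates at an adjusted p under 0.05 with sex as covariate. Each plate held 4 to 9 of the 28 date labels, so these differences were not separated from differences between dates. Plate explained a median of 15.6% of the variance of a VST gene, and it was therefore removed before co-expression was computed.

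Genes of cholesterol biosynthesis rose and fell together over mice. The lanosterol demethylase gene Cyp51 and the sterol desaturase gene Sc5d had the highest pair correlation, a Spearman rho of 0.926, and the median over 190 pairs of the 20 list members was 0.715. Positive values were found in 179 pairs and values over 0.5 in 158. Tm7sf2, a sterol reductase gene, had the lowest value, -0.251 against Ebp. Levels spread between mice by 1.93-fold for Hmgcs1, a synthase early in the pathway, as the ratio of the 90th to the 10th percentile. The mean rho of the list was 0.643, where 10000 random lists matched on expression had a median of -0.00320 and a maximum of 0.146 (permutation p = 0.0001, the smallest possible, adjusted p = 0.000220 over 22 lists). Within single plates the mean rho was 0.482 to 0.817, and it was 0.544 with collection date in place of plate.

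**Figure D2:**
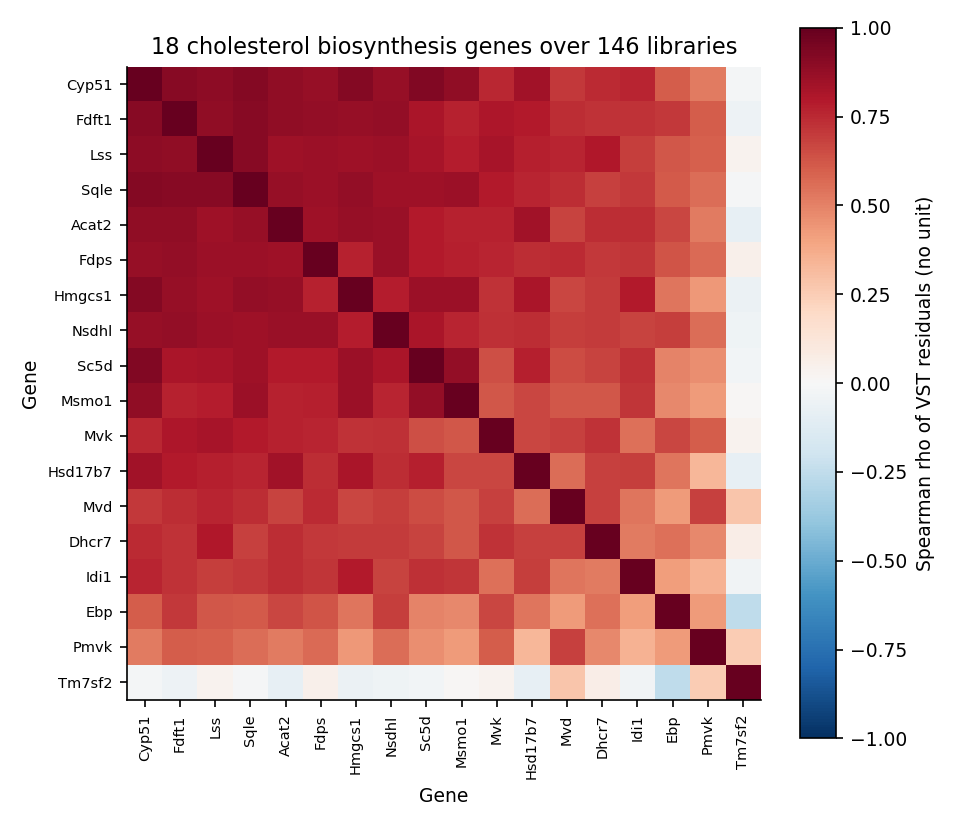
Spearman rho between each pair of 18 of the 20 cholesterol biosynthesis genes over 146 libraries, from VST values with plate and sex removed, ordered by mean rho. Colours run from blue at -1 to red at 1, and Tm7sf2 is the pale line at the edge, with a lowest value of -0.251 against Ebp.

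Other fixed lists were compared by the same measure. Interferon response genes had a mean rho of 0.839 and DNA replication genes of 0.779, both above the cholesterol list. The neutrophil list had 0.577, endoplasmic reticulum stress 0.565, mitosis 0.525 and MHC class II 0.506. Lower values were 0.321 for osteoclast markers, 0.320 for the integrated stress response, 0.304 for NRF2 targets, 0.264 for hypoxia and glycolysis, 0.259 for immediate early genes, 0.258 for fatty acid synthesis, 0.236 for lysosomal genes, 0.212 for inflammatory genes, 0.200 for alternative activation, 0.148 for LXR targets, 0.129 for wound repair and 0.116 for sterol sensing, each with an adjusted permutation p between 0.000220 and 0.0347. Heat shock genes (0.0392, adjusted p = 0.177), macrophage identity genes (0.0661, adjusted p = 0.123) and X escape genes (0.142, adjusted p = 0.0812) did not pass.

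Genes of sterol uptake, sterol sensing and lipid synthesis followed the cholesterol score, and genes such as Sdc1, Vegfa and Abcg1 went against it. Insig1, which retains the sterol sensor SCAP in the endoplasmic reticulum (chromosome 5, 28071363 to 28078662), had a slope of 0.37 ± 0.01 log2 units per SD of the score (SE, n = 146, adjusted p = 6.57e-56). Stard4, a sterol carrier, had 0.33, Fasn, fatty acid synthase, 0.31, Chst10, a sulfotransferase, 0.31 and Aacs, acetoacetyl-CoA synthetase, 0.27. Ch25h, cholesterol 25-hydroxylase, had 0.40 ± 0.09 (adjusted p = 2.82e-05), Uaca 0.30, Pla2g4a, cytosolic phospholipase A2, 0.28, Zranb3 0.27, Kcnj10, a potassium channel, 0.26 and Slc24a5, uncertain at 38.7% shared 50-mers, 0.32. The largest negative slopes were -0.57 ± 0.07 for the proteoglycan gene Sdc1 (adjusted p = 2.28e-12), -0.52 ± 0.07 for Vegfa, vascular endothelial growth factor A (adjusted p = 9.71e-10), and -0.43 ± 0.05 for Abcg1, a sterol efflux transporter (adjusted p = 2.00e-14). Thrombospondin 1 (Thbs1) had -0.42, Mefv, pyrin, -0.41, Cgnl1 -0.40, Arrdc3 -0.39, the caveolin gene Cav1 -0.38, Pla2g7 -0.37, fibronectin (Fn1) -0.35, Ankrd37 -0.35 and H2-Q6, uncertain at 35.4% shared 50-mers, -0.35.

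In all 6675 of 10893 genes were associated with the score, 3387 positively and 3288 negatively, and 19 of the 20 list members passed against the score of the others. Tm7sf2, with a slope of 0.00 and an adjusted p of 0.850 by limma, was the other. Cyp51 had the smallest p with a slope of 0.36, followed by Fdft1 (0.39, uncertain at 25.6% shared 50-mers), Lss (0.31) and Fdps (0.34, uncertain at 25.8%). Such a count was not particular to cholesterol genes, since 100 random lists matched on expression gave a median of 5110 genes, with a range of 52 to 7829 and 20 lists at 6675 or more. The first principal component of the other genes held 25.9% of the variance and had an absolute r of 0.523 with the score. After its removal 3352 genes passed and after removal of 5 components 1406, of which Insig1, Stard4, Fasn, Chst10, Aacs, Abcg1, Cgnl1, Arrdc3, Cav1 and H2-Q6 are examples. With 5 components removed the slopes of the other genes named above for their large slopes were past the threshold no longer, and those of Ch25h, Zranb3, Thbs1, Fn1 and Ankrd37 changed sign. The score did not follow depth, with r = 0.0548 (permutation p = 0.510) and rho = -0.0657 (permutation p = 0.431) against the log2 total count.

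Scores of whole lists followed the same lines. Over 146 libraries the fatty acid synthesis score had a Pearson r of 0.836 and a Spearman rho of 0.810 with the cholesterol score, and the sterol sensing and uptake score an r of 0.820 and a rho of 0.796. All 4 values had a permutation p of 1e-05, the smallest possible, and adjusted values of 2.62e-05 for r and 3e-05 for rho over 21 lists. In the fatty acid list 9 of 11 members were positively associated, 9 adjusted over the list alone, with Fasn and Acly (0.08) first. In the sterol sensing list 5 of 9 were positive and 3 negative, and 6 and 3 adjusted over the list alone, with Srebf2, the sterol-regulated transcription factor, at 0.15. Without the 2 mice farthest from the median score r was 0.820 and 0.807, and within plates it was 0.666 to 0.961 and 0.707 to 0.927, positive on 7 of 7 plates in both cases. LXR targets and efflux genes had an r of -0.581 and a rho of -0.500 (permutation p = 1e-05 for each, adjusted p = 2.62e-05 and 3e-05), -0.557 without the 2 mice, and -0.876 to 0.0751 within plates. Of 11 members 8 were negative, among them Mylip (-0.24), a ubiquitin ligase gene, and Abcg1, and 2 positive, among them Lpcat3 (0.11), with the same counts adjusted over the list alone.

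DNA replication genes had an r of 0.637 and a rho of 0.467, both at p = 1e-05, with an r of 0.581 without the 2 mice and of -0.246 to 0.845 within plates. All 15 members were positive, 15 adjusted over the list alone, with Mcm7 (0.18, uncertain at 24.9% shared 50-mers) and Mcm3 (0.18) as examples. With 5 components removed neither the DNA replication score nor the slopes of Mcm7 and Mcm3 were past the threshold. Mitosis genes had an r of 0.442 and a rho of 0.305 (p = 1e-05 and 0.000210), with 12 of 15 positive and 1 negative, and the same adjusted over the list alone, with Birc5 (0.12) and Aurkb (0.10) first. Endoplasmic reticulum stress genes had an r of 0.349 and a rho of 0.336 (p = 2e-05 and 6e-05), with 9 of 11 positive and 1 negative, the same adjusted over the list alone, and Pdia4 (0.19) and Sdf2l1 (0.19) first. With 5 components removed both slopes changed sign (-0.02 and -0.03) and the list r was -0.154, none of them past the threshold, and the mitosis r was 0.171, also no longer past it. Macrophage identity genes had an r of -0.549 and a rho of -0.524, both at p = 1e-05, with an r of -0.524 without the 2 mice and of -0.822 to -0.179 within plates, negative on 7 of 7. Of 10 members 6 were negative and 1 positive, the same adjusted over the list alone, among them the transcription factor gene Spi1 (-0.06). These members did not vary together beyond random lists, with a mean rho of 0.0661 (adjusted permutation p = 0.123). With 5 components removed the macrophage identity score was past the threshold no longer. Within plates the mitosis r was -0.316 to 0.885 and the endoplasmic reticulum stress r -0.206 to 0.881, and without the 2 mice they were 0.380 and 0.302.

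Wound repair and matrix genes, the list closest to the phenotype in the series title, had an r of -0.452 and a rho of -0.436 with the score, both at p = 1e-05. The r was -0.446 without the 2 mice and -0.780 to 0.00558 within plates. With 5 components removed it was 0.0211, of opposite sign and past the threshold no longer. Of 17 members 12 were negative and 2 positive, and 12 and 3 adjusted over the list alone, with Vegfa and Tgfbi (-0.13) first. Neutrophil and granulocyte precursor markers also fell with the score, with an r of -0.280 and a rho of -0.258 (p = 0.000570 and 0.00176), 5 of 9 negative, and Cxcr2 (-0.22) and Retnlg (-0.25) first, and 5 adjusted over the list alone. That r changed sign with the first component removed (0.106) and with 5 removed (0.135), not past the threshold, and with 5 removed the slope of Retnlg was 0.01 and that of Mmp8 went from -0.22 to 0.09 (adjusted p = 0.00886). MHC class II genes had an r of -0.363 and a rho of -0.314 (p = 3e-05 and 0.000170), 7 of 8 negative and 8 adjusted over the list alone, with H2-DMa (-0.18) and Ciita (-0.14) first. NRF2 targets had an r of -0.439 and a rho of -0.392, both at p = 1e-05, with 6 of 9 negative, and 6 adjusted over the list alone, Srxn1 (-0.10) and Nqo1 (-0.11) first. Osteoclast markers had an r of -0.328 and a rho of -0.256 (p = 4e-05 and 0.00200), lysosomal genes -0.266 and -0.205 (p = 0.00122 and 0.0136) and immediate early genes -0.213 and -0.170 (p = 0.00984 and 0.0400, the last at adjusted p = 0.0505). Their members were negative in 2 of 4, 6 of 13 and 5 of 12 cases and positive in 0, 2 and 1, and adjusted over the list alone the same but for 4 negative in the last list. Examples are Atp6v0d2 (-0.34), the cathepsin gene Ctsl (-0.24, uncertain at 25.9% shared 50-mers) and the phosphatase gene Dusp1 (-0.26). With 5 components removed the r of these 3 lists changed sign, to 0.106, 0.0957 and 0.0585, none past the threshold, and the slopes became 0.18 for Atp6v0d2 (adjusted p = 0.00785), 0.03 for Ctsl and -0.01 for Dusp1. MHC class II at -0.178 and NRF2 targets at -0.114 were then past it no longer. Without the 2 mice these 6 r values were -0.284, -0.317, -0.426, -0.295, -0.229 and -0.195. They were negative on 6, 5, 6, 5, 4 and 5 of 7 plates, with within-plate values from -0.935 to 0.276. Adjusted p over the 14 lists called lay between 2.62e-05 and 0.0148 for r, and between 3e-05 and 0.0505 for rho.

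The other 7 lists did not pass for r, from -0.155 for heat shock to 0.159 for interferon response, with adjusted p between 0.0772 and 0.909. The integrated stress response, at an r of 0.147, passed for rho (0.213, adjusted p = 0.0165). Between these lay the inflammatory list at -0.00950, alternative activation at -0.0725, hypoxia and glycolysis at -0.0440 and X escape genes at -0.0740. With 5 components removed 4 lists passed, of which 2 were among the 14, fatty acid synthesis at 0.778 and sterol sensing at 0.843. The others, interferon response at -0.315 and heat shock at -0.231, had not passed before, and interferon response changed sign. The LXR list lay at -0.112, macrophage identity at -0.181, DNA replication at 0.0848 and wound repair at 0.0211.

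**Figure D3:**
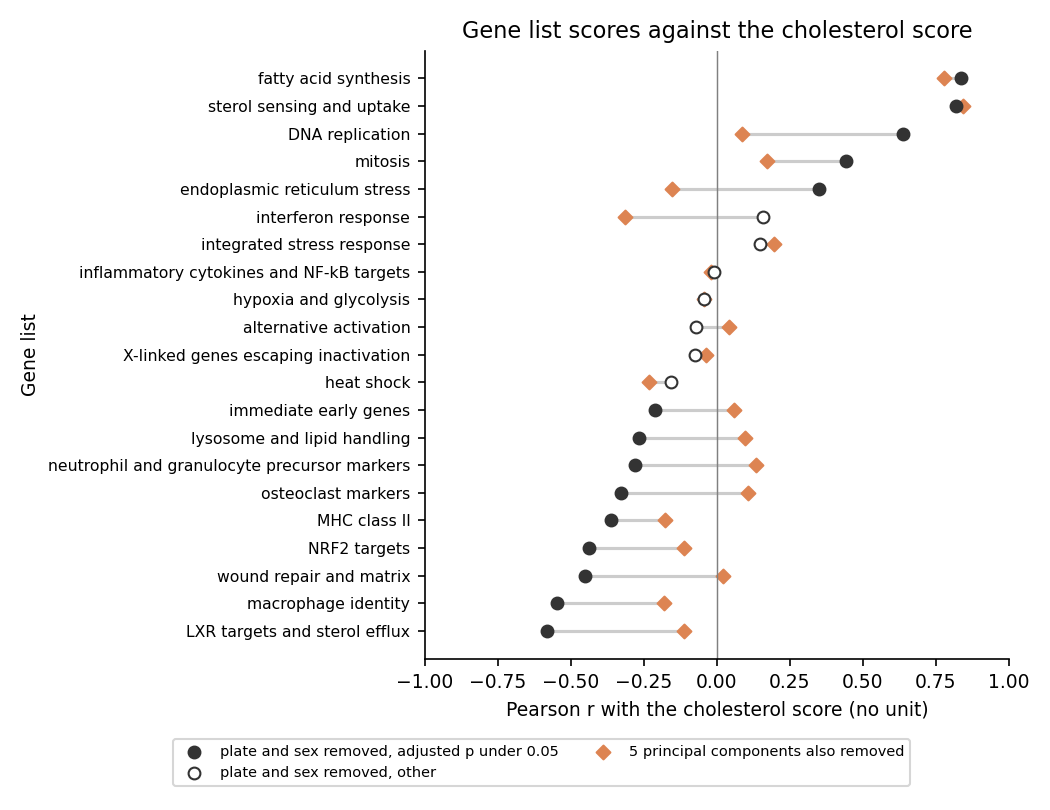
Pearson r of each of 21 list scores with the cholesterol score over 146 libraries, after removal of plate and sex (circles, filled at an adjusted permutation p under 0.05) and after removal of 5 principal components as well (diamonds). Fatty acid synthesis and sterol sensing stay at 0.778 and 0.843 with the components removed, while wound repair goes from -0.452 to 0.0211.

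Whether the cholesterol score differed between the labelled sexes depended on the batch label that was removed. From values with plate alone removed, females had a mean of 0.0792 ± 0.935 (SD, n = 86) and males of -0.113 ± 1.08 (SD, n = 60), a difference of 0.193 SD (permutation p = 0.255). With lane within plate removed and sex permuted within lane the difference was 0.417 (permutation p = 0.0128), with collection date in the same way 0.516 (permutation p = 0.00223) and without plate 2 0.385 (permutation p = 0.0396), and these were the 3 alternatives under which it passed, while 8 dates held mice of a single sex. Collection date explained 62.7% of the variance of the score and plate 19.8%, and date explained 44.6% beyond plate (permutation p = 1e-05, the smallest possible). The mean rho of the list was 0.608 within females and 0.637 within males, a difference of -0.0293 (permutation p = 0.566).

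Unsupervised clustering placed 18 of the 20 cholesterol biosynthesis genes in 1 module of 46 genes, out of 37 modules with 5583 genes (Fisher's exact p = 7.42e-43, adjusted p = 6.04e-40 over 814 tests of modules against lists). The genes closest to the module mean were Lss (chromosome 10, 76531588 to 76557138, r = 0.954), Fdft1 (r = 0.945), Cyp51 (r = 0.942), Acat2 (r = 0.935) and Stard4 (r = 0.929), and Fdps, Insig1 and Nsdhl followed. Fdft1, Fdps and Acat2, at 35.1%, are uncertain for shared 50-mers. The module also held 4 of 9 sterol sensing genes (among them Insig1, Stard4 and Srebf2) and 3 of 11 fatty acid synthesis genes (Fasn, Acly and Acsl3), at adjusted p of 4.68e-06 and 0.00103. Ebp and Tm7sf2 were the members outside it. With the tree divided at 0.7 the module grew to 1758 genes and with collection date removed to 1376, holding 19 and 16 list members.

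Among autosomal VST genes with a mean of at least 10 CPM, Rpl26 varied most between mice after removal of plate and sex. Its residual SD was 1.28 log2 units (uncertain at 25.4% shared 50-mers). Genes with fewer than 5 counts in some library, such as Arg1 and Fggy, have no VST values and were not ranked. Further SDs were 1.203 log2 units for Aoah (acyloxyacyl hydrolase), 1.18 for Thbs1, 1.08 for Ch25h, 1.06 for Vcan (versican), 1.05 for Vwf (von Willebrand factor), 1.04 for Atp6v0d2, 1.02 for Fn1, 1.02 for Vegfa, 1.01 for H2-Eb1, 1.00 for Sdc1 and 0.97 for Itgb3, where the median gene had 0.16. The ribosomal protein gene Rpl7a (1.10, uncertain at 37.05%) and the meiotic gene Msh5 (1.06) were also among the 15 with the highest SD, and Rpl26, Ch25h, Msh5, Vwf and H2-Eb1 were nearly silent in some libraries.

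In 12 of 8647 genes with a median of at least 10 CPM, some mice had few counted reads. Arg1, arginase 1, had a median of 16.9 CPM and under 0.1 of it in 20 libraries, Fggy in 17, Msh5 in 17, H2-Eb1, an MHC class II chain, in 10, Ifi27l2a in 9, Pianp in 9, Vwf in 8, and the oxysterol enzyme gene Ch25h and Raet1d in 5 each. Rpl26 was nearly silent in 22, Gm11127, named since it completes the count, in 8, and 1 identifier absent from the annotation in 32. Vwf (chromosome 6, 125546774 to 125686679) had a median of 94.0 CPM and at most 5.11 CPM in its 8 libraries. Arg1 ranged up to 469 CPM with 91 libraries at or above 0.5 of its median, whereas for Fggy 129 libraries lay at or above 0.5 of the median of 19.5 CPM and the 17 at no more than 0.901 CPM. For Arg1 and Ch25h only 1 library lay below the widest gap between neighbouring values, about 7.3- and 1.5-fold, so the cut marked no separate low group. For Rpl26 and Msh5, 30 and 25 libraries lay below the widest gap, more than the 22 and 17 counted. Rpl26, Gm11127 and Raet1d are uncertain, with 25.4% to 77.8% of 50-mers shared. No test was applied to this count.

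**Figure D4:**
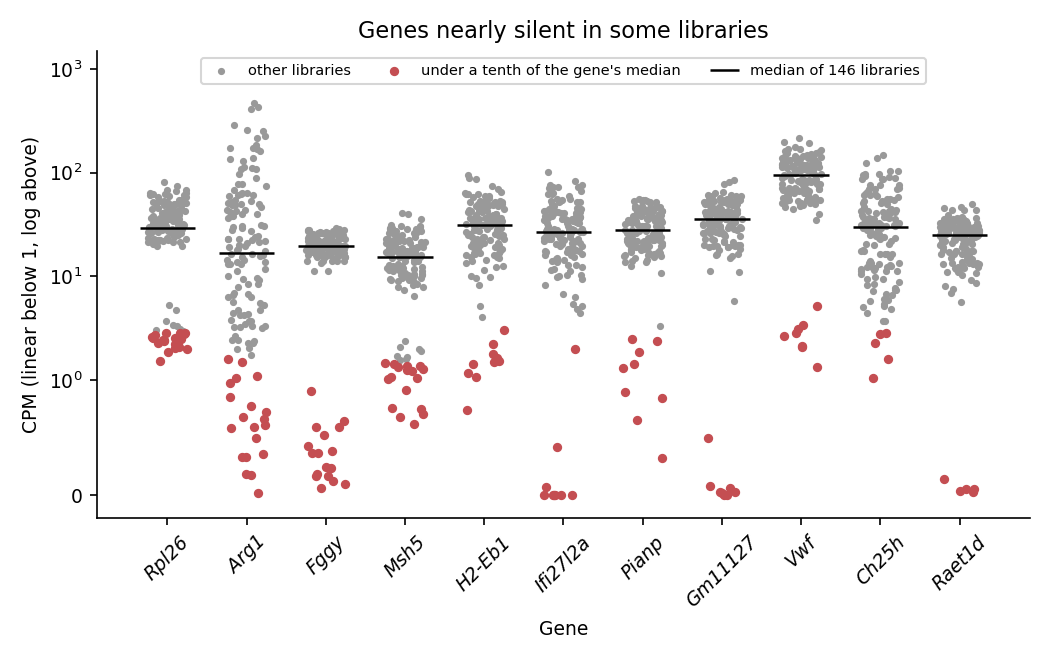
CPM of 11 genes in each of 146 libraries (linear below 1 and logarithmic above), with libraries under 0.1 of the median of the gene in red and the median as a line. Vwf lies at or under 5.11 CPM in 8 libraries against a median of 94.0 CPM, while Arg1 reaches 469 CPM in its highest library.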

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

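The tests of sex-linked counts, of the intermediate male library, of shared reads, of depth, of splits within collection dates and of splits without the 6 libraries were chosen only after the result was seen, whereas the overlap test of neighbouring genes and the other splits of the libraries were written before.

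The sex difference depended on the plate for Uty (adjusted p = 1.87e-11), Ddx3y (2.74e-11), Kdm5d (7.59e-11), Eif2s3y (7.94e-11) and Tcam1 (1.89e-05), each by the interaction term. The 4 Y-linked genes were no longer past the threshold without the 6 libraries against their label, and Tcam1 was set by male library 38 on plate 4. Of 30 splits of the libraries within plates, the real one included, 1 gave as many as the 5 genes, with a highest other of 3. Shuffled labels also lose the sex difference of the Y-linked genes itself, so these splits cannot decide whether chance gave this count. Without the 6 libraries 1 gene passed, and 15 of 30 splits gave as many, with a highest other of 3. These splits shuffle the labels in the same way, so they cannot decide on chance for what remains either.

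Libraries whose sex-linked counts went against their label are the first pattern. Mixed RNA of both sexes is argued against, because the lowest Y-linked sum of the 4 libraries labelled female was 91.3% of the male median. All 6 libraries lay nearer the other sex for each of Eif2s3x, Kdm6a and Kdm5c, so a mislabelled or swapped mouse is a candidate explanation, and plate 8 held libraries out of place in both directions. Male library 34 had 29.1% of the male median of Y-linked counts and a mean position of 27.6% of the way from female to male over the X escape genes, which may reflect RNA of both sexes mixed. Partial loss of the Y chromosome is argued against, since 3 of 3 X escape genes lay above each of the 57 other matching males.

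Genes at least 4-fold higher on plate 1 are the second pattern, with 11 such genes of at least 1 CPM there, 0 at least 4-fold lower there, and 2 higher on plate 10 and 1 on plate 4. Depth of plate 1 is argued against, since 11 of 11 genes stayed at 4-fold or more against the 22 libraries of other plates inside the depth range of plate 1, with a lowest ratio of 4.31. That test stands in place of one written before, the plate test with total count as covariate, which most genes pass and which could not tell. Their median share of 50-mers in other genes was 35.5%, where random lists matched on expression had a median of 0.468% and 1 of 10000 reached that share, so a difference in how shared reads were assigned could account for those with high shares. For 4 of the 11, Aldoart2, Stfa3, Gm17087 and Rasl2-9, the highest share was 2.59%, and no test of shared reads was made for them alone. The labels give no biological group that follows plate, with sex a covariate of the plate test, and no biological explanation was tested. Each plate held only some of the collection dates, so differences between plates were not separated from differences between dates.

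Nearly silent genes are the third pattern. Low depth is argued against, since the lowest count expected from the median of the gene in such a library was 373. Whether reads shared with annotated copies account for them cannot be told, since shares ran up to 7.23% in 8 genes and from 25.4% to 77.8% in Rpl26, Raet1d and Gm11127, and the share alone does not say where reads went. The bounds, 90% or more in each gene against under 20% in each, were set after the shares were known. Pairs of these genes within 2 Mb shared 56.2% of the smaller set of libraries on average (4 pairs) and pairs on different chromosomes 12.9% (50 pairs, permutation p = 0.00072, one-sided, though pairs share genes), with 8 of 8 for Pianp and Vwf, 6 of 8 for Msh5 and Gm11127, 5 of 10 for Msh5 and H2-Eb1, and 0 of 8 for H2-Eb1 and Gm11127. For the genes in these close pairs a local haplotype that gives few counted reads is a candidate explanation, as a hypothesis. Genotype was not analysed here, and no biological explanation was tested by the groups of the design. Arg1 and Ch25h, which had no separate low group, were in no pair within 2 Mb.

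For the number of genes that differed by sex, 605, 2 of 60 splits within plates gave as many, the real one included. Since another split gave more genes, the count within plates does not by itself exclude chance. The highest other split, in which 70 libraries changed sex, gave 1760 genes, and the next gave 323. Such a count points to a structure of the samples, of unknown source. With plate removed its labels had an absolute r of 0.313 with the first principal component of the VST values and 0.118 with the second, and the real labels 0.117 and 0.322, where 0.313 and 0.322 were the highest of the 60 on their components. Date explained 22.2% of its labels and a median of 19.7% over the splits. With collection date in place of plate, 1 of 60 splits within dates gave as many as the 666 genes of the real one. The highest other gave 4, which argues against chance for that count alone. Of the 666 genes 429 were among the 605, and the genes named for sex come from the model with plate. For the 8 gene lists called with the preset correlation, 16 of 60 splits gave as many, with a highest other of 15, so chance cannot be excluded. With an estimated correlation the highest other split gave 1 list where the real one gave 2. For plate, 1 of 30 splits gave as many as 9021 genes, with a highest other of 12. This argues against a chance placement of single libraries. The splits moved libraries regardless of collection date, so they cannot decide whether likeness between mice of the same date gave the count.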

How the results depend on the processing

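The alternatives without the 6 libraries against their label were planned for the sex count and chosen only after the result was seen elsewhere, as were those without male library 34 as well, and all others below were planned. Of the alternatives for main results 113 kept direction and side of the threshold or lay within 1.5 times. Of the rest 15 moved, 3 were stronger and 1 reversed. The plate count stayed at 8571 to 9708 in 6 alternatives, the mean rho of the cholesterol list at 0.482 to 0.817 in 28 and the cholesterol genes in their module at 16 to 19 in 8. The size of that module did not stay, with 34 to 1758 genes against 46, and 1376 with collection date removed. The cause was not tested where values moved, apart from fewer libraries or genes. The sex count of 605 became 948 with lane within plate, 926 without the 6 libraries, 976 without these and male 34, 356 without plate 3, 230 without plate 4 and 298 without plate 7. Called sex lists went from 8 to 2 with an estimated correlation, and interaction genes from 5 to 1 with voom and to 1 without the 6 libraries. Score genes went from 6675 to 3352 without the first component and 1406 without 5, and called list scores from 14 to 4 without 5, with 2 of the 14 kept. The sex difference in the score went from 0.193 to 0.417 with lane, 0.516 with date and 0.385 without plate 2, and reversed to -0.0791 without 5 components. Nearly silent genes numbered 21 at a median of 5 CPM, 23 under 0.2 of the median and 6 with at least 10 libraries, as these settings widen or narrow the definition.

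Of the list scores called in the main setting, those that reversed without 5 components were lysosomal genes (0.0957), wound repair (0.0211), endoplasmic reticulum stress (-0.154), immediate early genes (0.0585, and 0.127 without the first alone), neutrophil markers (0.135 and 0.106) and osteoclast markers (0.106 and 0.0709). Interferon response, not called there, also changed sign without 5 and passed in the new direction. Among slopes given in the report, those that reversed without 5 were Ankrd37 (0.00319), Ctsl (0.0278), Pdia4 (-0.0183), Retnlg (0.00676), Sdf2l1 (-0.0324) and Zranb3 (-0.0512), without either Atp6v0d2 (0.178, and 0.123 without the first alone), Ch25h (-0.0292 and -0.0919), Fn1 (0.0649 and 0.0560) and Thbs1 (0.0825 and 0.151), and without the first alone Ciita (0.0172) and Kcnj10 (-0.0104). The slope of Mmp8 reversed without 5 as well (0.0901). Of these Atp6v0d2 and Mmp8 without 5 and Thbs1 without the first passed in the new direction by limma (adjusted p = 0.00785, 0.00886 and 0.00517). Of 82 list members open to the naming rule 26 changed sign without 5, and 7 of them passed. Among single sex genes 655 alternatives kept the call, 61 lost it and 0 reversed, and among score genes 1135 kept it and 49 lost it. Depth limits the genes near 1 CPM, which hold about 14.5 counts in the shallowest library.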

Other observations

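No test here was chosen only after the result was seen, and the modules below come from the planned clustering.

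Other modules gathered further programmes of these macrophages. A module of 80 genes held 18 of 18 interferon response genes (adjusted p = 2.01e-37), with the antiviral genes Oasl2, Xaf1, Isg15 and Irf7 closest to its mean. A module of 97 genes around Top2a, a topoisomerase, and the kinesin gene Kif4 held 8 of 15 mitosis genes (adjusted p = 3.67e-11). The largest module, of 1323 genes, held 14 of 15 DNA replication genes (adjusted p = 3.10e-10) and 8 of 11 endoplasmic reticulum stress genes (adjusted p = 0.000555). The second largest, of 1273 genes around Btg1 and Hpse, heparanase, held Thbs1, Vegfa, Sdc1 and Atp6v0d2 of the most variable genes. Modules of 359 and 189 genes around Ptbp3 and Zfp646 were among the next in size, with no list enriched in them.

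A module of 160 genes around Ly6c2, Ccr2 and the haptoglobin gene Hp joined 8 of 9 granulocyte and precursor markers (adjusted p = 4.39e-12), among them Mpo, Elane, S100a8 and S100a9, with 4 of 8 MHC class II genes (adjusted p = 0.000349), H2-Aa, H2-Ab1, Cd74 and Ciita. Vcan and Fn1 were in the same module. Mpo ranged from 28.2 to 785 CPM over mice and S100a8 from 8.47 to 264 CPM. The modules with interferon, mitosis and granulocyte genes, and the genes named in them, were singled out after their values were seen.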
